A study of Mus musculus with 12 samples.

How the data were processed

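Bone marrow cells of mice were studied. The sorted cells carried GFP and were lineage-negative, Kit-positive and Sca-1-positive (LSK), a gate that holds blood stem cells and early multipotent progenitors. They came from secondary recipient mice that had been engrafted with donor stem and progenitor cells of 4 genotypes. These were wildtype (titled Empty), miR146aKO (titled Mir-146 KO/Empty, no miR-146a), Runx1mut (the frameshift mutant Runx1S291fsX300) and miR146aKO_Runx1mut (both). The sample titles do not say what Empty stands for or how the mutant Runx1 was brought into the cells. There were 3 libraries per genotype and 12 in all. Per the labels' protocols, RNA from the sorted cells was amplified to double-stranded cDNA by the Ovation v2 kit of NuGEN, and libraries were made with Nextera XT. Such libraries do not keep the strand of the RNA.

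The deposited table held raw read counts per gene symbol for 24421 symbols, with 1 column per library. Per the submitters' processing notes, FastQC 0.11.2, HISAT2 2.0.4, featureCounts 1.5.2 and the mouse build mm10 were used. The strand setting of the counting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. A deposited table named the genotype of each column without a replicate number, so libraries are named here by the identifier that heads their column. No column of the count table was left unused.

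Of the 24421 symbols, 23376 (95.7%) matched a gene in the GENCODE annotation of GRCm38 used here, which supplied coordinates and overlapping genes. The 13 mitochondrial genes of 1 list, and a few other list members such as Ighm, Trbc1 and Trbc2, were not analysed here. The 4 haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were listed at 0 in each of the 12 libraries. Because strand was not kept, reads of a gene and of an overlapping gene on the other strand cannot be told apart.

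Total counts per library ran from 3540043 to 7026393. The ribosomal RNA gene Rn45s took 3.91% to 17.8% of them. Spearman correlations of the counts between libraries ran from 0.738 to 0.892 (median 0.815) within a genotype and from 0.691 to 0.905 (median 0.766) between genotypes. A chi-square statistic per gene averaged 40.2 to 189 over all pairs of libraries, far above sampling noise, so no library was taken for a copy of another. The labels do not say that the libraries of a genotype came from separate animals, so p-values measure only the spread between these libraries. Amplified reads are not independent molecules, so counting intervals at 95% and floors of 3 counts cover counting error only.

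The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on the counts as deposited, with TMM scaling, the default low-count filter and 1 fit over all 12 libraries. The filter kept 12744 genes, and 5211 symbols had no count in any library. The common biological coefficient of variation was 0.809. The 6 contrasts were each altered genotype against wildtype, the double genotype against each single one, and the interaction. The interaction is the Runx1mut effect without miR-146a minus that with miR-146a. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM (library-size-scaled counts with TMM factors), as mean ± SD over 3 libraries.

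Gene lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over the 26 tested lists of each contrast. The alternatives were camera with an estimated correlation and the rotation test fry, whose p asks whether a list moves on balance one way. For miR146aKO against wildtype the estimated correlation ran from 0.005 for RUNX1 targets to 0.769 for erythroid genes. It was 0.424 for B lineage and 0.561 for stem cell genes. For lists so far above the preset, camera p-values with the preset are too small. The lists covered miR-146a targets, RUNX1 targets, NF-kB response, Toll-like and IL-1 receptor pathway, interferon response and MHC class I and class II. They also covered stem cell genes, Hoxa and Meis genes, lymphoid priming, cell cycle, p53 targets, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, glycolysis and immediate early genes. Marker lists stood for megakaryocyte, erythroid, neutrophil, monocyte and macrophage, dendritic, B, T and NK, mast and basophil, and stromal and endothelial cells. Genes can sit in more than 1 list. A list level is the mean over its tested genes of log2 CPM with a prior count of 2.

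The design, the gene lists, the first set of other settings and the rule for named genes were fixed before the data were examined. The rule took, per contrast, up to 8 rising and 8 falling called genes of largest fold change whose libraries did not overlap, with mean log2 CPM of at least 2 and without predicted gene models. It added up to 3 called members per list, and always Runx1, Traf6, Irak1, Irak2 and Mir146. All other called genes, the uncalled examples within lists (mostly those with the smallest p) and Kit, Ly6a, Jchain, Dok3, B3gnt5, Ddx3y and Sh2d1b1 where uncalled were chosen after their values were seen.

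Alternatives were RLE scaling, other count filters, DESeq2 1.42.0, limma-voom, fits on the compared genotypes only and leaving out each library. Added after seeing the data were fits without Rn45s, with a Y-linked covariate (mean log2 CPM of 4 Y-linked genes), with robust dispersion and with all libraries thinned to 3540043 counts. The main test, camera with the preset correlation and fry were tried on simulated data for each compared pair of genotypes. The test of miR-146a seed sites was tried for miR146aKO against wildtype. The interaction, the alternatives and the other checks were not tried so. Simulated genes varied independently, so the list tests were not tried on correlated genes. With 50 genes per fold size changed among 12744, in the comparison of miR146aKO with wildtype the main test recovered 4% of genes changed 4-fold, 42% at 16-fold, 72% at 64-fold and 84% at 256-fold. It made 3 false calls among 12504 unchanged genes. In the comparison of Runx1mut with wildtype it recovered 8%, 46%, 78% and 90% at the same fold sizes.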

Results

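The data are 12 RNA-seq libraries of GFP-positive LSK cells sorted from the bone marrow of secondary recipient mice, 3 for each of 4 genotypes. Total counts were 4387524 to 6642886 in wildtype, 3540043 to 4353971 in miR146aKO, 5417624 to 7026393 in Runx1mut and 4907029 to 6522388 in miR146aKO_Runx1mut. The miR146aKO libraries were thus the shallowest group. The design asks what loss of miR-146a, a microRNA that restrains innate immune signalling, and a truncating mutation of Runx1, a transcription factor of blood development, do alone and together.

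The altered genes were examined first. Mir146 (chromosome 11, 43374397 to 43374461, minus strand, GRCm38) had 0 counts in 11 libraries, including all 6 labelled as having intact miR-146a. It had 14 counts in library A031, labelled miR146aKO_Runx1mut. With 0 counts where miR-146a is intact, 0 counts elsewhere check no label, and the 14 counts go against the label of A031, which was kept as given. Runx1 (chromosome 16, 92601466 to 92826149) was measured at 279 ± 69.8 CPM (SD, n = 3) in wildtype, 374 ± 211 in Runx1mut, 139 ± 36.3 in miR146aKO and 190 ± 69.5 in miR146aKO_Runx1mut. A count per gene does not show the frameshift, nor would it tell an introduced copy of Runx1 from the cell's own gene. Runx1 was not called in any of the 6 contrasts. The known miR-146a targets Traf6, Irak1 and Irak2, which carry Toll-like and IL-1 receptor signals, were not called in any contrast either. Irak2 stood at 5.46 ± 2.61 CPM in wildtype and 44.1 ± 9.51 in miR146aKO (edgeR adjusted p = 0.126), and Traf6 at 102 ± 43.6 and 94.3 ± 26.1.

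Loss of miR-146a alone gave 23 called genes in the main test, against 0 to 3 in the other 5 contrasts, but with a Y-linked covariate it gave 0, and without A015, A053 or A151 no more than the double genotype against miR146aKO (5, 2 and 2). In miR146aKO libraries 19 genes were higher and 4 lower than in wildtype by edgeR, while DESeq2 had 558 higher and 288 lower, limma-voom 70 and 6, and edgeR without a count filter 544 and 252. Cd2, an adhesion receptor of lymphocytes, rose from 0.0475 ± 0.0822 to 85.5 ± 8.86 CPM (SD, n = 3), and Cd79b, a signalling chain of the B cell receptor, from 16.1 ± 4.28 to 499 ± 327. Ptprc, which encodes the leukocyte surface protein CD45, rose from 317 ± 58.5 to 1153 ± 101, and Itgb2, the beta chain of leukocyte integrins, from 49.8 ± 27.9 to 348 ± 80.8. Gas2l3, a cytoskeletal linker that acts in cell division, fell from 189 ± 17.2 to 35.4 ± 8.32.

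The largest changes among called genes included lymphocyte and phagocyte genes. Rasgrp1, an activator of Ras in lymphocytes, rose by 7.86 ± 1.36 on the log2 scale (SE, edgeR adjusted p = 0.0397). Slc11a1, a metal transporter of macrophage phagosomes, rose by 7.61 ± 1.40 (adjusted p = 0.0493), and Grap, an adaptor of lymphocyte receptors, by 6.92 ± 1.13 (adjusted p = 0.0322). Asb2 rose by 7.43 ± 1.29, Akap12 by 8.08 ± 1.47 and Card6 by 4.78 ± 0.82. Sh2d1b1, an adaptor of NK cell receptors, had 481 counts in miR146aKO and 0 in wildtype. This was 265-fold higher against a floor of 3 counts over the group, with a lower 95% counting bound of 215-fold. For Cd2 (chromosome 3, 101275899 to 101287939) the 966 counts against 1 gave a ratio of 1595 (95% counting interval 286 to 63079). Tmem40 had 1 count in miR146aKO and 556 in wildtype, a ratio of 0.00297 (7.51e-05 to 0.0166), and Zfp111 fell by 4.84 on the log2 scale (SE 0.81).

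Among the remaining called genes were Hvcn1, a voltage-gated proton channel, from 14.6 ± 4.13 to 208 ± 59.3 CPM, and Dok3, an adaptor of B cells and myeloid cells, from 3.30 ± 1.20 to 83.6 ± 14.8. Ets1, a transcription factor of lymphocytes and the called member of the RUNX1 target list, rose by 3.40 ± 0.63 on the log2 scale, and Sh2b3, which restrains cytokine signalling, by 2.18 ± 0.40. Ext2, an enzyme of heparan sulphate synthesis, rose from 73.0 ± 8.82 to 509 ± 126 CPM. Ero1lb, Nedd9 and Filip1l also rose, and 1700025G04Rik fell. Hvcn1 overlaps Tctn1, Grap overlaps Slc5a10, Sh2b3 overlaps Atxn2 and Filip1l overlaps Cmss1 on the other strand, and Ext2 overlaps Alx4, so these values can hold reads of both genes.

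**Figure D1:**
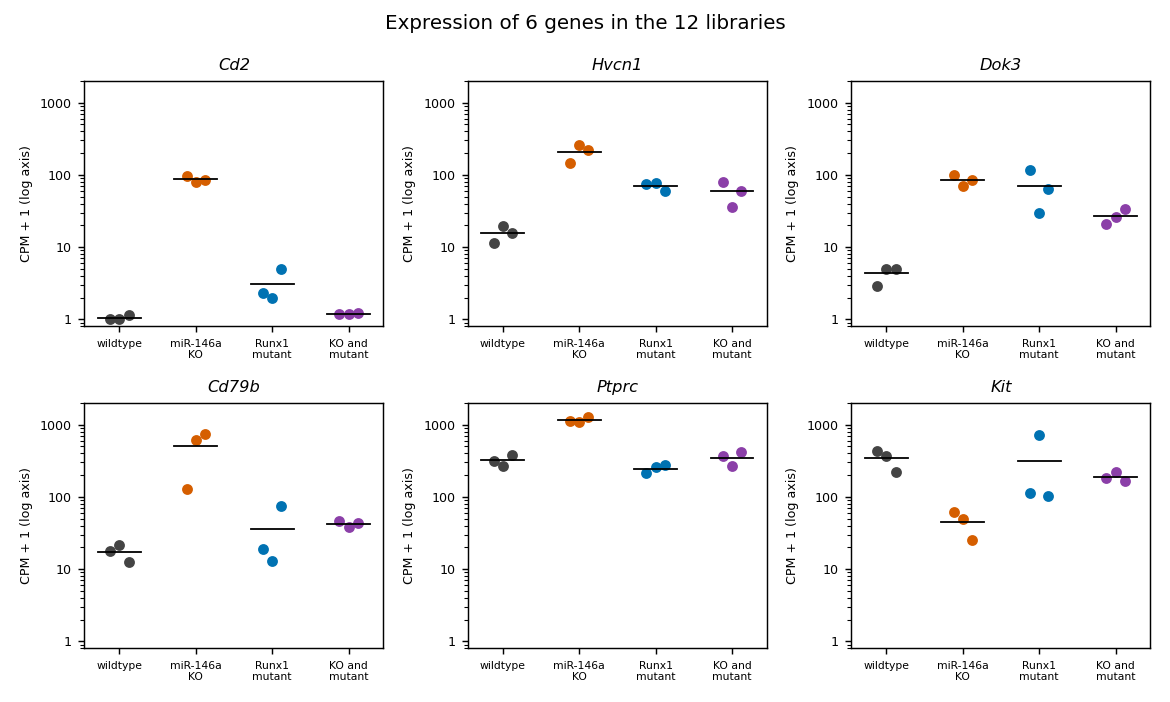
Each panel plots 1 gene, with the 4 genotypes on the x axis and CPM plus 1 on a logarithmic y axis. Points are libraries and lines are genotype means. The 3 miR146aKO libraries lie above the 3 wildtype libraries for Cd2, Hvcn1, Dok3, Cd79b and Ptprc, and below them for Kit.

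Genes of several classes of mature blood cells were higher in this contrast. All 17 measured B lineage genes were on the higher side in miR146aKO, with 10 adjusted over the list alone and 1, Cd79b, over all genes (camera adjusted p = 4.81e-11). The list level was 6.39 ± 1.84 in miR146aKO and 1.31 ± 1.17 in wildtype. Cd22 stood at 327 ± 235 against 0.803 ± 1.06 CPM and Blk, a kinase of B cells, at 89.7 ± 81.7 against 0.0949 ± 0.164, neither called over all genes. The plasma cell gene Jchain reached 7025 ± 3828 CPM against 152 ± 253 (edgeR adjusted p = 0.201). The 10 MHC class II genes had 9 higher adjusted over the list alone and 0 over all genes (camera adjusted p = 2.68e-09), with H2-Ab1 at 2720 ± 1858 against 154 ± 77.0 CPM and Cd74 at 3827 ± 2265 against 175 ± 82.2. Of 23 monocyte and macrophage genes 16 were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 1.35e-09), with C1qb at 721 ± 633 against 12.6 ± 20.8 CPM and Mpeg1 at 576 ± 404 against 37.9 ± 13.5. With an estimated correlation, adjusted p was 0.170 for B lineage, 0.170 for MHC class II and 0.236 for monocyte and macrophage genes. Libraries of the genotypes overlapped for monocyte and macrophage genes, with A047 of miR146aKO at 4.635 under A040 of wildtype at 4.845 (mean log2 CPM).

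Markers of 4 further cell classes were higher by camera. Of 15 T and NK genes 6 were higher adjusted over the list alone and 1, Cd2, over all genes (camera adjusted p = 0.000283), and of 14 stromal and endothelial genes 9 adjusted over the list alone and 0 over all genes (0.000431). For 11 dendritic genes the counts were 3 and 0 (0.000767), and for 19 erythroid genes 4 and 0 (0.0268). These adjusted p became 0.262, 0.267, 0.170 and 0.719 with an estimated correlation, and with a Y-linked covariate erythroid genes were on the lower side (camera adjusted p = 0.2144). Neutrophil genes, with 12 of 23 on the higher side, and mast and basophil genes, with 5 of 9, were not past the threshold (camera adjusted p = 0.684 for both). The libraries of this genotype differed in which markers they held. T and NK genes were at 6.82 in A047, 3.29 in A150 and 2.14 in A151, while stromal genes were at 0.082, 4.30 and 3.79 and erythroid genes at 0.389, 4.79 and 3.31 (mean log2 CPM), the first under the 3 wildtype libraries at 0.544 to 1.717. Cd3e, a chain of the T cell receptor complex, was at 644 CPM in A047, 8.71 in A150 and 2.68 in A151.

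Several inflammatory and signalling lists were higher as well, while interferon response genes had 17 of 36 on the higher side (camera adjusted p = 0.896). Of 29 NF-kB response genes 8 were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 1.31e-07, 0.0680 with an estimated correlation). Nfkbia, the inhibitor that NF-kB induces, stood at 150.9 ± 37.8 against 37.0 ± 12.9 CPM, and the list level was 4.43 ± 0.41 against 2.53 ± 0.42. Immediate early genes had 3 of 23 higher adjusted over the list alone and 0 over all genes (1.29e-05), and the Toll-like and IL-1 receptor pathway 6 higher and 1 lower of 34 over the list alone and 0 over all genes (0.00184). Lymphoid priming had 1 of 16 adjusted over the list alone and 0 over all genes (0.000615), and MHC class I 0 of 12 by either adjustment (0.0323). The adjusted p of these 4 lists was 0.262, 0.189, 0.189 and 0.342 with an estimated correlation.

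Stem cell and proliferation genes were lower. Of 28 stem cell genes 27 were on the lower side, with 1 adjusted over the list alone and 0 over all genes (camera adjusted p = 1.35e-08). The member Vwf was at 3.66 ± 3.41 against 206 ± 196 CPM and was not called. Of 35 cell cycle genes 14 were lower adjusted over the list alone and 0 over all genes (8.46e-08), with Top2a at 216 ± 55.5 against 767 ± 433 CPM. Ribosome biogenesis genes had 4 of 26 lower adjusted over the list alone (1.03e-06) and megakaryocyte genes 4 of 18 (0.00909), with 0 over all genes in both. Ribosomal proteins (1.25e-06), Hoxa and Meis genes (0.000195) and glycolysis genes (0.000615) were lower with 0 members called by either adjustment. In the order given, adjusted p with an estimated correlation was 0.262, 0.267, 0.262, 0.647, 0.267, 0.262 and 0.236. Libraries of the genotypes overlapped for cell cycle, ribosome biogenesis and ribosomal protein genes. The cell cycle level was 5.616 in A015 of wildtype, within miR146aKO at 5.278 to 5.639 (mean log2 CPM). The gate's own markers went opposite ways, with Kit at 44.0 ± 17.9 against 339 ± 111 CPM (edgeR adjusted p = 0.0725) and Ly6a, which encodes Sca-1, at 755 ± 258 against 142 ± 87.0 (adjusted p = 0.218).

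Of the 26 lists, 8 had all 3 miR146aKO libraries above all 3 wildtype libraries and 4 had them below, where chance gives 10% of lists. Sex-linked transcripts also differed, with a Y-linked mean of 24.8 to 60.4 CPM in the miR146aKO libraries and 0.14 to 7.99 in wildtype, and a Y-linked covariate left 0 of the 23 calls at an adjusted p under 0.05, with a median log2 fold change of the 19 higher genes of 4.21 (SE 0.97) in place of 4.66 (SE 0.76) (2026 genes had an unadjusted p under 0.05 in the main test). Without A053 or A151 the count was 2, without A150 it was 3, without A015 or A040 it was 5, without A001 it was 61, without A042 it was 95 and without A047 it was 125.

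**Figure D2:**
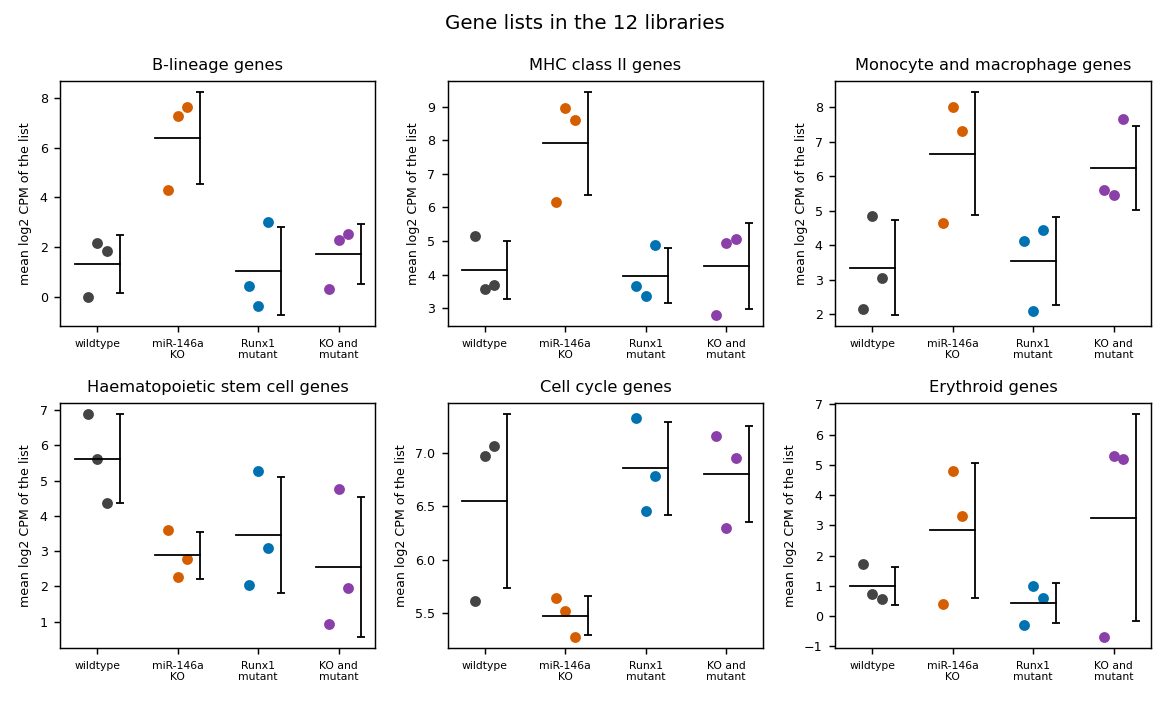
Each panel plots 1 gene list, with the 4 genotypes on the x axis and the mean log2 CPM of the list on the y axis. Points are libraries, lines are genotype means and error bars are SD (n = 3). B lineage genes lie at 4.28 to 7.64 in the miR146aKO libraries and at or under 3.01 in the other 9.

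The Runx1 mutation alone was compared with wildtype. Stem cell genes were lower in the Runx1mut libraries, with 26 of 28 on the lower side and 2 lower adjusted over the list alone (camera adjusted p = 6.50e-12). Mllt3, a regulator of stem cell self-renewal, stood at 32.2 ± 40.5 against 251 ± 130 CPM (SD, n = 3), and Vwf at 3.88 ± 4.25 against 206 ± 196. Interferon response genes were lower in 31 of 36, with 1 adjusted over the list alone (8.56e-06), and Ifitm3, an antiviral membrane protein, was at 97.8 ± 78.3 against 679 ± 232 CPM. Hoxa and Meis genes were lower in 15 of 18 (0.00172). None of these members was called over all genes, and adjusted p with an estimated correlation was 0.815 for each of the 3 lists. Library A042 lay within the wildtype range for each of them (mean log2 CPM). It was at 5.265 for stem cell genes (wildtype 4.362 to 6.888) and 3.685 for interferon response genes (3.631 to 5.191). For Hoxa and Meis genes it was at 4.902 (3.564 to 5.246).

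Of the 5 lists on the higher side, immediate early genes had 5 of 23 adjusted over the list alone (camera adjusted p = 0.00241), with Fosb at 447 ± 335 against 96.1 ± 44.7 CPM. Their level was 6.182 in A042 and 5.902 in A058, but 4.036 in A021, under the 3 wildtype libraries at 4.042 to 5.494 (mean log2 CPM). Mast and basophil genes had 2 of 9 (0.0341), with Hdc, the histamine-forming enzyme, at 249 ± 107 against 9.60 ± 11.3 CPM. Neutrophil genes were higher in 21 of 23 (0.0136), with S100a9 at 4902 ± 6514 against 550 ± 190. The neutrophil level was 8.269 in A021 and 7.251 in A058, but 4.45 in A042, under the 3 wildtype libraries at 5.257 to 6.375 (mean log2 CPM). Over all genes A042 was closer to A015 of wildtype (Spearman 0.905) than to A021 (0.849) and A058 (0.847). Ribosomal proteins (0.00265) and oxidative phosphorylation genes (0.0156) had 0 members called by either adjustment, as had the neutrophil list. In the order immediate early, mast, neutrophil, ribosomal protein and oxidative phosphorylation, adjusted p was 0.839, 0.815, 0.878, 0.878 and 0.878 with an estimated correlation.

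No single gene was called in Runx1mut against wildtype by edgeR, where 704 genes had an unadjusted p under 0.05 (447 without A021 and 467 without A058) and 637 would by chance. DESeq2 called 117, limma-voom 0 and edgeR without a count filter 162. The smallest adjusted p was 0.0830, for Dok3 at 69.4 ± 44.9 against 3.30 ± 1.20 CPM and for B3gnt5, a glycosyltransferase, at 2.38 ± 0.97 against 43.3 ± 13.9. Without A042, 1 gene was called, and without A015, 5 lists in place of 8 passed. Of 26 lists 0 separated the 3 Runx1mut libraries from the 3 wildtype libraries, where chance gives 10%.

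The double genotype was compared with wildtype. All 28 stem cell genes were on the lower side in miR146aKO_Runx1mut (camera adjusted p = 5.55e-13), with Mllt3 at 38.9 ± 22.1 against 251 ± 130 CPM (SD, n = 3) and Nkx2-3 at 0.289 ± 0.358 against 30.0 ± 17.0. The list level was 0.926 in A001 and 1.949 in A051, but 4.77 in A031, within wildtype at 4.362 to 6.888 (mean log2 CPM). Monocyte and macrophage genes were on the higher side in 22 of 23 (3.85e-10), with Tyrobp, a signalling adaptor of myeloid cells, at 319 ± 209 against 63.8 ± 46.3 CPM. Neutrophil genes were higher in 22 of 23 (0.000192), with Gfi1, a transcription factor of granulocyte development, at 281 ± 177 against 54.5 ± 15.7. None of these members was called, over all genes or adjusted over the list alone. Adjusted p with an estimated correlation was 0.588 for stem cell and for monocyte and macrophage genes and 0.624 for neutrophil genes.

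Erythroid genes were higher in this contrast, with 5 of 19 adjusted over the list alone and 0 over all genes (camera adjusted p = 0.0196). Car1, carbonic anhydrase of red cell precursors, stood at 403 ± 349 against 0.927 ± 0.978 CPM, and the list level was 5.28 in A031, 5.19 in A051 and -0.701 in A001. The Toll-like and IL-1 receptor pathway was higher with 1 of 34 adjusted over the list alone (0.0485), with Tlr7 at 67.1 ± 68.8 against 1.91 ± 2.45 CPM. Oxidative phosphorylation (1.63e-05), immediate early (0.00148), ribosomal protein (0.0199), NF-kB response (0.0199) and ribosome biogenesis genes (0.0485) were higher, and Hoxa and Meis (0.000172) and interferon response genes (0.00148) lower, with 0 members called by either adjustment. All 12 lists of this contrast had an adjusted p of 0.588 or more with an estimated correlation.

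No gene was called in miR146aKO_Runx1mut against wildtype by edgeR, with 1201 at an unadjusted p under 0.05. DESeq2 called 192, limma-voom 0 and edgeR without a count filter 256. The smallest adjusted p was 0.282, for Sh2d1b1 with 283 counts against 0 in wildtype, at least 114-fold higher. The NF-kB and the monocyte and macrophage lists separated the 3 libraries from the 3 wildtype libraries, 2 of 26 lists where chance gives 10%. Ribosome biogenesis genes turned to the lower side without A001 (camera adjusted p = 0.953).

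The double genotype was then compared with Runx1mut, which asks what loss of miR-146a adds to the mutation. Monocyte and macrophage genes were on the higher side in 22 of 23, with 4 adjusted over the list alone (camera adjusted p = 1.05e-11). The complement gene C1qb of macrophages stood at 457 ± 545 against 2.07 ± 1.56 CPM (SD, n = 3) and Cd68 at 180 ± 200 against 25.2 ± 6.14. Erythroid genes were on the higher side in 18 of 19, with 11 adjusted over the list alone (8.42e-07), and Car1 was at 403 ± 349 against 0.370 ± 0.346. Stromal and endothelial genes had 6 of 14 adjusted over the list alone (0.00422), with Cxcl12, a chemokine of marrow stroma, at 156 ± 270 against 0.408 ± 0.367 CPM. Cxcl12 was on the lower side without A031, and stromal genes were at 3.55 in A031, 0.11 in A001 and 0.416 in A051. With an estimated correlation the adjusted p was 0.8185 for each of these 3 lists.

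Ribosome biogenesis (camera adjusted p = 0.000773), oxidative phosphorylation (0.0123) and NF-kB response genes (0.0356) were higher and stem cell genes lower (0.0393), with 0 members called by either adjustment. The stem cell member Vwf went the other way, at 53.6 ± 47.4 against 3.88 ± 4.25 CPM, and the list turned to the higher side without A042 or without A001. All 7 lists had an adjusted p of 0.819 or more with an estimated correlation. No gene was called over all genes by edgeR, with 590 at an unadjusted p under 0.05 (1095 without A031, the library with Mir146 counts, and 407 without A051) and a smallest adjusted p of 0.763, while DESeq2 called 78, limma-voom 0 and edgeR without a count filter 144. The number of lists was 12 without A021 or A058 and 4 without A051. The NF-kB and the monocyte and macrophage lists, 2 of 26, had the 3 double libraries above the 3 Runx1mut libraries, where chance gives 10%.

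The double genotype was compared with miR146aKO, which asks what the Runx1 mutation adds where miR-146a is lost. This contrast shares the 3 miR146aKO libraries with miR146aKO against wildtype, so what sets these libraries apart moves both in opposite ways. Median log2 fold changes of B lineage genes were 4.95 there, -4.919 here and 0.175 for the double genotype against wildtype. MHC class II genes had 4.24, -3.984 and 0.396. Cells of other types in the miR146aKO libraries and an effect of the mutation cannot be told apart here. Cd2 fell from 85.5 ± 8.86 to 0.197 ± 0.0391 CPM (SD, n = 3), 3 counts against 966, a ratio of 0.00228 (95% counting interval 0.000469 to 0.00667, edgeR adjusted p = 0.00756). Ext2 fell from 509 ± 126 to 35.5 ± 20.5 CPM (adjusted p = 0.00756). All 17 B lineage genes were on the lower side, with 8 adjusted over the list alone and 0 over all genes (camera adjusted p = 1.72e-12), and Cd79b was at 41.7 ± 4.26 against 499 ± 327 CPM. All 10 MHC class II genes were on the lower side, with 8 adjusted over the list alone and 0 over all genes (1.14e-09), and H2-Ab1 was at 180 ± 137 against 2720 ± 1858. T and NK genes had 8 of 15 lower adjusted over the list alone and 1, Cd2, over all genes (4.16e-05). Adjusted p with an estimated correlation was 0.1542, 0.1542 and 0.2182 for these 3 lists.

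Proliferation genes were higher in the double genotype than in miR146aKO. Against wildtype, the median log2 fold change of cell cycle genes was -1.252 in miR146aKO and 0.323 in the double genotype. Of 35 cell cycle genes 17 were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 2.97e-11), with Cenpf, a kinetochore protein, at 323 ± 147 against 54.9 ± 5.05 CPM. Ribosome biogenesis genes had 8 of 26 (3.83e-11), with Ncl, nucleolin, at 4673 ± 1616 against 1666 ± 562. Glycolysis genes had 4 of 21 (2.35e-05), with Pkm at 532 ± 270 against 166 ± 31.8. Megakaryocyte genes had 7 of 18 (0.0148), with Itga2b, the platelet integrin chain, at 403 ± 452 against 9.13 ± 6.06, and neutrophil genes 1 of 23 (0.0274). The megakaryocyte level was 6.302 in A031 and 6.047 in A051, but 0.687 in A001, under the 3 miR146aKO libraries at 1.852 to 2.697 (mean log2 CPM). All 61 ribosomal protein genes were on the higher side with 0 called by either adjustment (1.72e-12), and oxidative phosphorylation genes in 45 of 48 likewise (3.09e-07). In the order cell cycle, ribosome biogenesis, glycolysis, megakaryocyte, neutrophil, ribosomal protein and oxidative phosphorylation, adjusted p with an estimated correlation was 0.2391, 0.1657, 0.1542, 0.6455, 0.6455, 0.1795 and 0.2628.

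Lower in this contrast were also dendritic genes (camera adjusted p = 8.46e-05, 1 of 11 adjusted over the list alone), lymphoid priming (0.000220, 3 of 16) and NF-kB response (0.00210, 1 of 29). Interferon response (0.00429, 1 of 36) and MHC class I genes (0.0159, 0 of 12) were lower too, and no member of these 5 lists was called over all genes. With an estimated correlation the adjusted p of all 15 lists was 0.148 or more. Fry put 7 of the 15 at an adjusted p of 0.0461 or less, which were dendritic, B lineage, MHC class II, lymphoid priming, NF-kB response, ribosomal protein and ribosome biogenesis genes. Of 26 lists 4 had the double libraries above and 8 below the miR146aKO libraries, where chance gives 10%. Without A001 no gene was called, without A015 or A051 there were 5 and without A021 there were 6, against 2 in the main test (1882 had an unadjusted p under 0.05). RLE scaling called 13, limma-voom 12, DESeq2 645 and edgeR without a count filter 549.

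The interaction contrast tested whether the Runx1 mutation acted differently with and without miR-146a. It too includes the miR146aKO libraries, so cells of other types in them would move it as well. Cd2, Dok3 and Hvcn1 were called, each lower in the double genotype than the separate effects add up to. Dok3 was at 3.30 ± 1.20 CPM in wildtype, 83.6 ± 14.8 in miR146aKO, 69.4 ± 44.9 in Runx1mut and 25.9 ± 6.37 in the double genotype (SD, n = 3, interaction -6.08 ± 0.84 SE on the log2 scale, edgeR adjusted p = 0.0257). Hvcn1 was at 14.6 ± 4.13, 208 ± 59.3, 68.7 ± 9.53 and 57.9 ± 21.9 CPM (-4.07, adjusted p = 0.0457). Cd2 was at 0.0475 ± 0.0822, 85.5 ± 8.86, 2.07 ± 1.62 and 0.197 ± 0.0391 CPM (adjusted p = 0.00202).

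The lists on the lower side of the interaction were B lineage (camera adjusted p = 2.33e-05, 4 of 17 adjusted over the list alone), MHC class II (2.33e-05, 4 of 10), immediate early (0.000605, 4 of 23), T and NK (0.000878, 8 of 15 lower and 1 higher), lymphoid priming (0.0141, 1 of 16) and NF-kB response (0.00457, 0 of 29). On the higher side were ribosome biogenesis (7.72e-10, 6 of 26), cell cycle (1.33e-06, 1 of 35), stem cell (0.00271, 1 of 28), megakaryocyte (0.0157, 1 of 18), ribosomal protein (0.00011), glycolysis (0.000858), oxidative phosphorylation (0.0104) and Hoxa and Meis genes (0.0222), the last 4 with 0 members called. Over all genes Cd2 was the called list member. With an estimated correlation the adjusted p of all 14 lists was 0.413 or more. Leaving out each library in turn, Cd2 stayed called in all 12 fits, Dok3 when A042 was left out and Hvcn1 in none. The count was 6 without A042, 2 without A051 and 1 without each of the other 10 libraries, limma-voom called 0, and with a Y-linked covariate there were 2, of which Cd2 was shared with the 3 (1206 genes had an unadjusted p under 0.05 in the main test, and DESeq2 called 168).

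Fold changes were also compared between backgrounds, using contrasts that share no library. Across 12744 genes, the Runx1mut effect with and without miR-146a had Pearson r = 0.063 (jackknife SE 0.132 over libraries) and Spearman rho = 0.080, with the same sign in 53.5%. The miR-146a effect with and without the Runx1 mutation had r = 0.198 (SE 0.180) and rho = 0.081, with the same sign in 52.3%. Neither r exceeded 2 SE, and genes are not independent replicates. At an unadjusted p under 0.05 in both contrasts, 182 genes went the same way and 37 opposite ways for the miR-146a effect, and 103 and 65 for the Runx1mut effect. The single contrasts had 2026 and 590 such genes for miR-146a and 704 and 1882 for Runx1mut. Monocyte and macrophage and erythroid lists were higher by camera in both miR-146a contrasts. Whether cells of these types account for the 182 was not tested. Overlap of called genes was not compared, since 1 contrast of each pair had 0 called genes by edgeR (704 and 590 at an unadjusted p under 0.05, and DESeq2 called 117 and 78).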

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

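The tests of depth and of sex and the adjustment over second lists were chosen only after the results they bear on were seen, and the other tests of this part before.

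The interaction test picked out 3 genes whose Runx1mut effect differed between the miR-146a backgrounds. The interaction was -6.08 on the log2 scale for Dok3 and -4.07 for Hvcn1. The fitted value for Cd2 was -13.41, but 1 wildtype count and 3 counts in the double genotype make its size depend on the prior count of the fit. Of 100 splits of the 12 libraries into 4 groups of 3, the real one included, 1 gave 3 or more genes (the highest other gave 1). A random grouping of all libraries thus rarely gave such a count, but this does not exclude chance for the interaction. The other splits mix genotypes, so they do not test the interaction apart from the separate effects, and the count was 1 when any of 10 of the 12 libraries was left out (2 without A051, 6 without A042) and 0 with limma-voom. With a Y-linked covariate Cd2 stayed called. The call of Dok3 ended as the fold shrank and its error grew (-6.08, SE 0.84, to -5.5, SE 1.07, adjusted p = 0.302), and that of Hvcn1 as its error grew (-4.07, SE 0.61, to -4.2, SE 0.85, adjusted p = 0.344). For lists chance cannot be excluded, since 23 of the 100 splits gave 14 or more lists and the highest other gave 17. In the other data, Mir146 had 14 counts in library A031, labelled as lacking miR-146a, against 0 in the other 11 libraries, which goes against the label of A031. Stromal genes were also higher in A031 (3.55) than in A001 (0.11) and A051 (0.416, mean log2 CPM). Cells of other types were not tested as a source of the Mir146 counts.

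Genes of several classes of mature cells were higher in the miR146aKO libraries, although a Lin-negative, Kit-positive, Sca-1-positive gate would remove most such cells. Lower depth of these libraries is argued against for the 23 called genes only, since 22 of them were called again with all libraries thinned to equal depth. They had been picked as called in the same counts, which favours a second call. Of the members of the marker lists that were higher, only Cd79b and Cd2 were among them, so this does not settle the wider pattern. Sex of the animals cannot be told apart from the loss of miR-146a. Over the 109 members of the 7 marker lists that were higher, miR146aKO minus wildtype was 3.19 (SE 0.76, mean log2 CPM). It was 2.63 (SE 1.15, 95% interval -0.07 to 5.34) with Y-linked class in the fit, which rests on 2 Runx1-mutant libraries with few Y-linked transcripts against 4 with many. The 7 lists were taken because camera put them higher in these same libraries. A difference above 0, here and list by list, thus partly follows from that choice and is no separate evidence of a rise. List by list, without adjustment for 7 lists, the interval lay above 0 for B lineage (5.53, 0.96 to 10.1) and dendritic genes (3.4, 0.78 to 6.03) and held 0 for the other 5, where erythroid genes turned to -1.02 (-6.27 to 4.23) beside a Y-linked effect of 2.86 (SE 1.61). With a Y-linked covariate the median log2 fold change of the 19 higher called genes went from 4.66 (SE 0.76) to 4.21 (SE 0.97), and the calls ended as the fold fell and its error grew. Cells of other types in the sorted fraction and an untested effect of miR-146a loss within LSK cells cannot be told apart either. Stromal genes were at 0.082 in A047, within wildtype at -0.277 to 0.418, but at 4.297 in A150 and 3.789 in A151. Erythroid genes were at 0.389, 4.791 and 3.312 in these libraries. For these genes this argues against an equal effect of genotype in all 3 libraries. B lineage, dendritic and T and NK genes were higher than in wildtype in all 3, where the question stays open. Only dendritic genes were at a like level in the 3, at 5.346 to 5.701. T and NK genes were at 6.819 in A047, 3.29 in A150 and 2.14 in A151, and B lineage genes at 4.276, 7.269 and 7.638. These unequal levels do not show an equal effect of genotype either. The second B cell list separated the libraries of the 2 genotypes, and the second macrophage list did not, with the lowest miR146aKO library at 3.09 under the highest wildtype library at 3.53 (mean log2 CPM). By camera with an estimated correlation, over 3 second lists, the adjusted p was 0.047 for B cell and 0.148 for macrophage genes, where both had to be under 0.05.

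For the 5 comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real split of miR146aKO and wildtype called 23 genes and 19 lists, and the highest other split 0 genes and 12 lists. For the double genotype against miR146aKO the values were 2 genes and 15 lists, against 1 and 14. Of Runx1mut and wildtype the real split called 0 genes and 8 lists, and other splits up to 5 genes and 14 lists. For the double genotype against wildtype these values were 0 and 12, against 1 and 13, and against Runx1mut 0 and 7, against 1 and 14. The splits with as many lists as the real one were 6, 1, 3, 8 and 1 of 10 for Runx1mut, miR146aKO and the double genotype against wildtype, and for the double genotype against Runx1mut and miR146aKO.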

How the results depend on the processing

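The fits without Rn45s, with a Y-linked covariate, with robust dispersion and at equal depth, and leaving out libraries for lists and correlations, were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate number. The counts of genes called are given in the order Runx1mut, miR146aKO and the double genotype against wildtype, the double genotype against Runx1mut and miR146aKO, and interaction, where the main test gave 0, 23, 0, 0, 2 and 3. Without a filter on low counts they were 162, 796, 256, 144, 549 and 268, and with DESeq2 117, 846, 192, 78, 645 and 168. With limma-voom they were 0, 76, 0, 0, 12 and 0. A fit on the compared genotypes only called 195 genes for miR146aKO against wildtype and 5 for the double genotype against miR146aKO. That last count was 13 with RLE scaling, 11 without Rn45s, 14 with robust dispersion and 9 at equal depth. At equal depth 1 gene was called for Runx1mut against wildtype, and with the Y-linked covariate 0 for miR146aKO against wildtype. The causes of these differences were not tested. With the covariate the median fold of the higher called genes fell and its error grew. The fit on miR146aKO and wildtype only called more genes although it holds fewer libraries.

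Leaving out each library moved the gene counts from 0 to 1 (without A042) for Runx1mut against wildtype and from 2 (A053, A151) to 125 (A047) for miR146aKO against wildtype. They ran from 0 (A001) to 6 (A021) for the double genotype against miR146aKO, from 1 to 6 (A042) for the interaction, and stayed at 0 for the 2 other contrasts. For lists they ran from 5 (A015) to 10 (A058) of the 8 for Runx1mut against wildtype and from 4 (A051) to 12 (A021, A058) of the 7 for the double genotype against Runx1mut. With an estimated correlation 0 lists were called in each contrast. With fry there were 4 for miR146aKO against wildtype, 7 for the double genotype against miR146aKO and 0 elsewhere. The Y-linked covariate left 12 of 19 lists for miR146aKO against wildtype and 9 of 14 for the interaction.

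The reversals concerned values that were not called, apart from 3 lists. With the Y-linked covariate Irak1 (-0.012), Runx1 (-0.276) and Ms4a2 (-0.511) turned negative for Runx1mut against wildtype, and erythroid genes turned for miR146aKO against wildtype (adjusted p = 0.2144). The Runx1 interaction was -0.014 with RLE scaling and -0.014 with DESeq2. Leaving out libraries, the log2 fold change for Runx1mut against wildtype ran from -0.125 to 0.435 for Irak1, -0.124 to 0.716 for Runx1 and -0.561 to 0.183 for Traf6. For miR146aKO against wildtype it ran from -0.371 to 0.181 for Irak1 and -0.370 to 0.296 for Traf6. For the double genotype against Runx1mut it ran from -0.983 to 9.21 for Cxcl12 and -0.062 to 0.354 for Irak1, and for the interaction from -0.036 to 0.550 for Irak1 and -0.278 to 0.577 for Runx1. The camera adjusted p ran from 4.99e-05 to 0.953 for ribosome biogenesis in the double genotype against wildtype and from 1.71e-05 to 0.949 for stem cell genes against Runx1mut. RLE and DESeq2 scaling moved the median of all genes by less than 0.1. Depth limits genes with few counts: the ratio of Cd2 has a counting interval from 286 to 63079.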

Other observations

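The test of the miR-146a seed below was chosen before its result was seen, and the adjustment over 3 second lists after.

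Second lists of cell markers that shared no gene with the first were written before their values were seen and compared between miR146aKO and wildtype. All 14 B cell genes were on the higher side, 11 of them adjusted over the list alone and 0 over all genes, at a list level of 7.29 ± 1.32 against 3.02 ± 0.39 (mean log2 CPM, SD over 3 libraries). All 15 macrophage genes were on the higher side, 15 adjusted over the list alone and 0 over all genes, at 6.88 ± 3.28 against 2.33 ± 1.14. The lowest miR146aKO library at 3.09 lay under the highest wildtype library at 3.53. Abundant members were the lysosomal protease gene Ctsb at 1990 against 130 CPM and the mannose receptor gene Mrc1 at 1290 against 18.2. All 8 further progenitor genes were on the lower side, 3 adjusted over the list alone and 0 over all genes, at 5.17 ± 0.60 against 7.44 ± 0.25. The B cell list separated the genotypes, with the lowest miR146aKO library at 5.76 and the highest wildtype library at 3.48. Camera with an estimated correlation, adjusted over the 3 lists, gave an adjusted p of 0.047 for B cell, 0.148 for macrophage and 0.0605 for progenitor genes. The stem and progenitor surface marker gene Cd34 was at 45.2 against 205 CPM.

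Lists of regulatory targets were not past the threshold of camera in any of the 6 contrasts. Of 17 miR-146a targets 3 were higher in miR146aKO than in wildtype adjusted over the list alone and 0 over all genes, and the smallest camera adjusted p of the list over the 6 contrasts was 0.415. Camera placed this list on the higher side there, while the median and the mean of its fitted fold changes lay below 0. Its level separated the double genotype, at 4.482 to 4.708, from miR146aKO, at 4.73 to 5.372 (mean log2 CPM), where chance gives 10%, and overlapped in the 4 other comparisons of 2 genotypes. Of 27 RUNX1 targets, most of which sit in other lists too, 4 were higher and 2 lower in the same contrast adjusted over the list alone and 1, Ets1, over all genes, and the smallest adjusted p was 0.317. Of 23 p53 targets 1 was higher adjusted over the list alone and 0 over all genes, and the smallest adjusted p was 0.410.

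Erythroid genes set libraries apart within the 2 genotypes that lack miR-146a. Their level was 4.79 in A150 and 3.31 in A151 of miR146aKO and 5.28 in A031 and 5.19 in A051 of the double genotype (mean log2 CPM), against 1.72 or less in the other 8 libraries. The haemoglobin genes were listed at 0 in these libraries too.

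Sex-linked transcripts varied within genotypes. Xist, which is made in female cells, was at 704 to 4452 CPM in wildtype, 16.5 to 464 in miR146aKO, 20.9 to 2772 in Runx1mut and 52.9 to 1814 in the double genotype. The mean of 4 Y-linked genes was 6.55 CPM in A058 of Runx1mut and 3.44 in A001 of the double genotype, and 33.6 to 53.5 in the other 4 libraries of these genotypes. Ddx3y, a Y-linked helicase, stood at 0.628 ± 0.624 CPM in wildtype, 51.7 ± 20.8 in miR146aKO, 30.9 ± 15.2 in Runx1mut and 35.5 ± 41.4 in the double genotype (SD, n = 3). Libraries such as A151 and A042 held both Xist, at 464 and 348 CPM, and Y-linked transcripts, at 24.8 and 42.4 CPM. In A040 of wildtype these were at 2903 and 7.99 CPM. The Y-linked covariate and class therefore need not measure the sex of the animals alone, and the source of both transcripts in 1 library was not tested.

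A hypothesis was that genes with a miR-146a seed site, the heptamer AGTTCTC, in the 3' UTR would be higher without miR-146a. Of 11623 tested genes with a 3' UTR, 1496 had a site, among them 9 of the 17 searched genes of the target list. The coefficient of the site was -0.081 on the log2 scale in miR146aKO against wildtype, at percentile 7.4 among 4098 heptamers found in a similar number of genes. In the double genotype against Runx1mut it was -0.039, at percentile 20.6. Both lay within the middle 95% of other heptamers (-0.109 to 0.123 and -0.088 to 0.085), so a general rise of genes with a site was not seen and a small one stays open. In simulated data an added shift of 0.1 reached percentile 96.6 in the first contrast. Those data shuffled the fold changes over genes, which removes any link of fold change with the 3' UTR or with cell type. The real contrast, where markers of other cell types differ, may thus be less sensitive. The seed is shared with miR-146b.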
